A study of Mus musculus with 4 samples.

How the data were processed

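RNA sequencing of polyadenylated RNA was re-analysed for 4 mouse libraries with a single genotype label, KRasEtv wt. Per the labels' protocols, alveolar type II cells, the surfactant-making cells of the lung alveolus, were sorted from lungs as cells with EpCAM on their surface and without CD24, CD45, CD31 and podoplanin. The sorted cells were grown in matrigel in BEGM, a medium for bronchial epithelium, with 100 nM 4-hydroxytamoxifen for 4 days and for 1 more day without it, and RNA was then taken. The design text names 3 genotypes with 4 mice each; which of the 3 the label KRasEtv wt stands for is not stated in the labels, and genotypes other than it were not analysed here. The labels give no sex of the mice. The 4 libraries carry no replicate number in their labels, so replicates 1 to 4 are names given in accession order, and library 1 below means replicate 1. The labels do not tie single libraries to single mice. P-values of tests over the 4 libraries and of the per-gene test therefore rest on the spread between these libraries, which may in part be technical. P-values of gene lists and of the ribosomal protein genes come from resampling genes and do not measure that spread.

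The authors deposited a table per library with 28096 gene identifiers and 2 values for each. Per the file headers, the count is the number of reads that aligned uniquely to the gene model. Per the file headers, the second value is a size-factor-adjusted RPKM (nRPKM), which is a count scaled for library size and gene length. Per the submitters' processing notes, GSNAP and the mm9 build were used. Versions, the gene annotation, strand use and filters are not given in the sources used here. From the values themselves, the deposited RPKM equals the count times a factor for the library, divided by a length for the gene.

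Gene symbols were looked up by Entrez identifier in a RefSeq gene table of another mouse assembly, GRCm38.p6, which was used for names only, so no coordinates are given. A symbol was found for 25035 identifiers. Identifiers without a symbol took from 2.48% to 3.71% of the counts of a library. Uniquely aligned reads miss sequence that a gene shares with a copy elsewhere. The percent of the 50-base words of each gene's longest protein-coding transcript that also occur in another annotated gene was therefore computed from the GRCm38 transcripts.

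Total counts were 12133251, 12987938, 12928901 and 13591876 in libraries 1 to 4. A count of 0 allows up to 3 counts, which is 0.247, 0.231, 0.232 and 0.221 CPM in the same order. Intervals of shares are 95% Wilson intervals. Intervals and floors cover counting error only, since PCR copies were not marked.

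Levels are the deposited nRPKM, and logarithms are log2 of nRPKM plus a pseudocount of 1, which understates differences of genes with low levels. Differences between genes or lists within a library were tested with two-sided exact sign-flip permutation tests over the 4 libraries, whose smallest possible p is 0.125. The 4 comparisons of Epcam with the genes used for exclusion were adjusted by Benjamini-Hochberg. The design of a single group leaves no contrast between conditions.

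Before the data were examined, 31 gene lists with 346 different genes were fixed, covering ETS factors, the sort gate, both alveolar epithelial types, transitional epithelium, other cell types of the lung, signalling outputs and pathways. Of their genes, 2 (Hmgcs1 and Hbb-bt) are not analysed here. The level of each list was described by the percentile of its median among 10000 random lists of the same size. The genes named were also set by rule: all members of the PEA3, gate, type II and type I lists, the 3 highest members of each other list, the 10 highest genes, the called variable genes with a mean level of at least 5, and the 3 most variable members of each list that varied. A few genes are not reported here. Genes named outside this rule were chosen after their values were seen and are given as such.

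Spread between libraries was tested per gene on the counts with edgeR 4.0.16 in R 4.3.3. A quasi-likelihood model with an intercept only was fitted after TMM scaling and filterByExpr, which with a single group keeps only genes with enough reads in every library, and the ratio of each gene's quasi-dispersion to the trended prior was tested against the F distribution with Benjamini-Hochberg adjustment at 0.05. On simulated counts for 13156 genes, of which 200 were changed in a single library, this recovered 2% of 4-fold, 36% of 8-fold, 66% of 16-fold and 70% of 32-fold changes. It called 1 gene that had not been changed, and 1 gene in a simulation without changes. For 24 lists with at least 3 members at a level of 1 or more in at least 2 libraries, the SD over libraries of the list's mean was compared with 10000 random lists matched on level in 20 bins, one-sided, with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates, so this describes these libraries.

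Alternatives were another pseudocount (0.1), CPM without length correction, TMM or median-ratio scaling, other filters, a non-robust prior, dispersion outliers of DESeq2 1.42.0, 5 bins and leaving out each library in turn. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.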

Results

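The transcriptome of cultured mouse alveolar type II cells was measured in 4 libraries of the label KRasEtv wt. The series concerns Etv target genes; the other genotypes of its design text were not analysed here, so levels and spread within this label are described. Between 12133251 and 13591876 reads were counted per library, and 10888 of 28096 genes had a level of at least 1 nRPKM (size-factor-adjusted RPKM) in all 4 libraries. Replicates were alike across genes, with a median Pearson r of 0.983 for log2 levels (range 0.977 to 0.984 over 6 library pairs). Counts of each pair differed by 39.0 to 113 times sampling noise (chi-square over degrees of freedom), so no table repeats another, but this does not tell separate mice from separate preparations. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 had the highest levels and took 23.0%, 35.1%, 19.6% and 38.9% of counts in libraries 1 to 4. Next came Sftpc at 10006 ± 3649 nRPKM, Sftpb at 3065 ± 1133, the actin-binding thymosin Tmsb4x at 2428 ± 597 and the nuclear noncoding RNA Malat1 at 1975 ± 834 (SD, n = 4). An unnamed identifier (100503054) had nearly the counts of Tmsb4x, and the mitochondrial CYTB (1757 ± 885), Lyz2 (1663 ± 381) and the mitochondrial ND1 (1593 ± 810) completed the 10 highest genes.

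Of the PEA3 subfamily of ETS transcription factors, which gives the series its title, Etv5 was the predominant member. Etv5 (Entrez 104156) had 26.3 ± 9.63 nRPKM, Etv4 (18612) had 1.79 ± 0.226 and Etv1 (14009) had 1.02 ± 0.521 (SD, n = 4). Etv5 therefore exceeded Etv4 by 14.5 ± 3.86 times and lay above it in all 4 libraries. Etv5 had 16.2, 37.2, 31.3 and 20.6 nRPKM in libraries 1 to 4, from 1260 to 2522 reads, and Etv4 rested on 59 to 98 reads. The log2 difference of Etv5 and Etv4 was 3.23 ± 0.43 (two-sided exact sign-flip permutation test, p = 0.13, the smallest p that 4 libraries allow). Etv5 minus Etv1 was 3.72 ± 0.47, with the same p of the exact permutation test. Etv5 and Etv1 share 26.8% and 18.7% of their 50-base words with another gene and Etv4 shares none, so the levels of Etv5 and Etv1 are uncertain. Levels of different genes rest on the authors' gene lengths. In CPM, which has no length correction, the difference of Etv5 and Etv4 was 4.31.

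Etv5 also had a higher mean level than each of the 23 other ETS genes listed, 15 of which had a mean level of at least 1. Ets2 followed with 14.8 ± 2.21 nRPKM, Elk3 with 14.6 ± 2.36 and Elf1 with 13.6 ± 3.08 (SD, n = 4). These differences were not tested, and in library 1 Etv5 (16.2) lay below Ets2 (17.4). No read was counted for Etv2, Erg, Fev or Spic, so any expression was below the detection limit of these libraries. The median of the other ETS genes lay above 96.4% of random lists and that of the PEA3 genes above 70.3%.

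**Figure D1:**
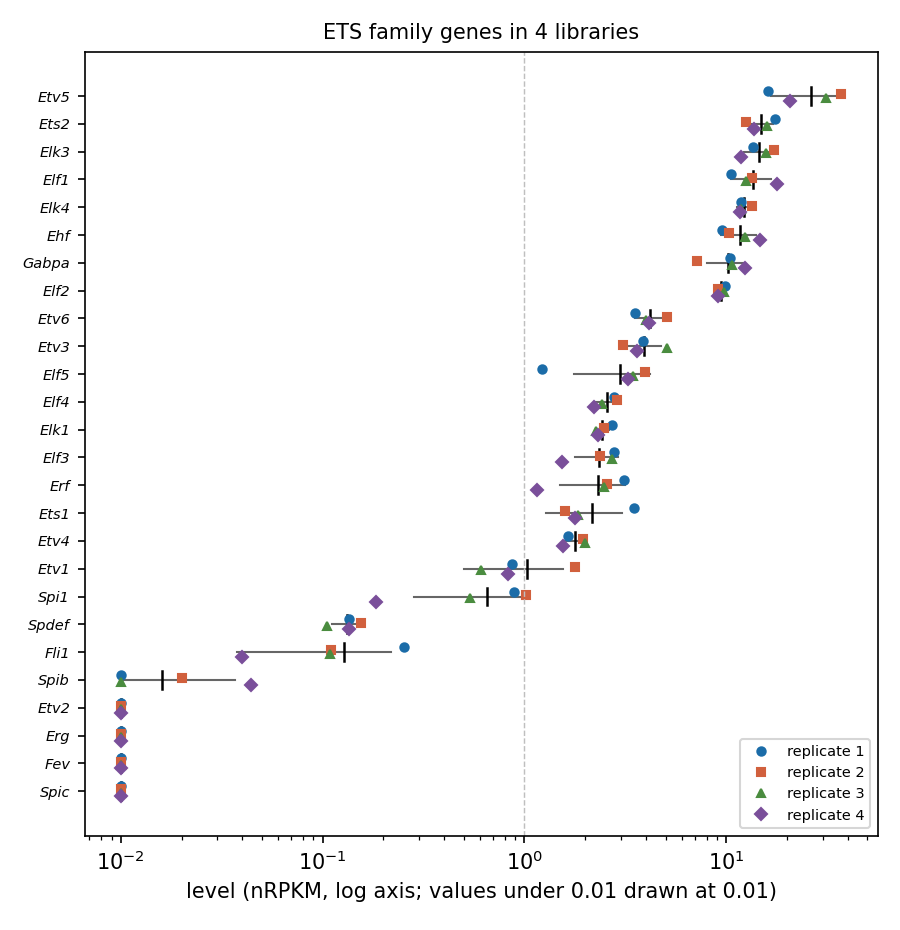
Levels of the 26 ETS family genes (nRPKM, log axis, values under 0.01 drawn at 0.01) in the 4 libraries, with symbols for replicates, a vertical tick for the mean, a horizontal line for the mean ± SD and a dashed line at 1. Etv5 has the highest mean, 26.3, and Etv4 and Etv1 lie near 1.79 and 1.02.

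The genes of the sort gate were compared as RNA after culture. The gate itself used surface protein before culture, so these levels cannot tell whether the cells still matched it. The epithelial adhesion gene Epcam was high at 54.1 ± 3.47 nRPKM, whereas the leukocyte gene Ptprc (CD45) had 0.423 ± 0.193 and the endothelial gene Pecam1 (CD31) had 0.112 ± 0.0625 (SD, n = 4). Transcripts of the other excluded surface proteins were present: Cd24a had 30.9 ± 13.2 nRPKM and Pdpn, the gene of podoplanin and a type I cell marker, had 21.1 ± 5.34. Epcam lay above each of the 4 genes in 4 of 4 libraries. The log2 differences were 5.63 ± 0.10 to Pecam1, 5.28 ± 0.17 to Ptprc, 1.35 ± 0.35 to Pdpn and 0.89 ± 0.56 to Cd24a. Each had p = 0.13 in the two-sided exact permutation test and an adjusted p of 0.13, the smallest possible. With a pseudocount of 0.1, the differences to the near-absent Pecam1 and Ptprc grew to 8.04 and 6.76.

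Alveolar type II markers had the highest median of the 31 lists, 161 ± 43.8 nRPKM (SD, n = 4). All 20 had a mean level of at least 10 nRPKM and 14 had at least 100. The surfactant protein genes Sftpc (10006 ± 3649), Sftpb (3065 ± 1133), Sftpa1 (335 ± 121) and Sftpd (285 ± 92.5) were abundant, and so were the lysozyme gene Lyz2 (1663 ± 381), the lung chemokine gene Cxcl15 (1527 ± 404) and the phosphate transporter gene Slc34a2 (905 ± 330). Egfl6 (212 ± 81.7), S100g (207 ± 75.4), the phospholipid enzyme gene Lpcat1 (182 ± 60.9), Lamp3 (154 ± 51.3), Napsa (150 ± 45.1), Il33 (117 ± 12.4) and Chil1 (102 ± 41.9) also reached 100. The lung lineage factor gene Nkx2-1 had 94.6 ± 32.7 nRPKM, Muc1 94.4 ± 51.1, the lipid transporter gene Abca3 51.5 ± 15.5, Cebpa 37.5 ± 12.9, Hc 26.8 ± 13.6 and Lyz1 21.3 ± 10.4 (SD, n = 4 throughout). Lyz1, Lyz2, Abca3 and Napsa share 16.1%, 15.4%, 14.3% and 10.9% of their 50-base words with another gene, so their levels are uncertain.

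Type I markers, of the flat cells that line the alveolus, were also expressed but lower. A mean level of at least 1 was found for 13 of 16, at least 10 for 11 and at least 100 for 4. The highest were Gprc5a (223 ± 50.7 nRPKM), the water channel gene Aqp5 (185 ± 15.6), the receptor gene Ager (156 ± 48.1) and Emp2 (116 ± 20.7). Akap5 (62.4 ± 10.4), Clic5 (43.5 ± 13.4), Hopx (29.97 ± 4.72), Vegfa (18.4 ± 1.21), Cav2 (16.2 ± 3.81), Col4a3 (15.2 ± 3.12) and Cav1 (11.6 ± 2.31) were intermediate. Col4a4 (4.65 ± 0.968) and Sema3e (4.36 ± 0.626) were low, and Rtkn2 (0.376 ± 0.198) lay below 1 on 12 to 40 reads. Spock2 (0.0910 ± 0.0533) rested on 1 to 9 reads, and Igfbp2 (0.0324 ± 0.0647) on 0 to 3, at or below the floor (SD, n = 4). The median type II marker exceeded the median type I marker by 3.06 ± 0.50 on the log2 scale, in 4 of 4 libraries (two-sided exact permutation test, p = 0.13, the smallest possible). Restricted to members at a level of at least 1 in a library, the difference was 2.43.

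**Figure D2:**
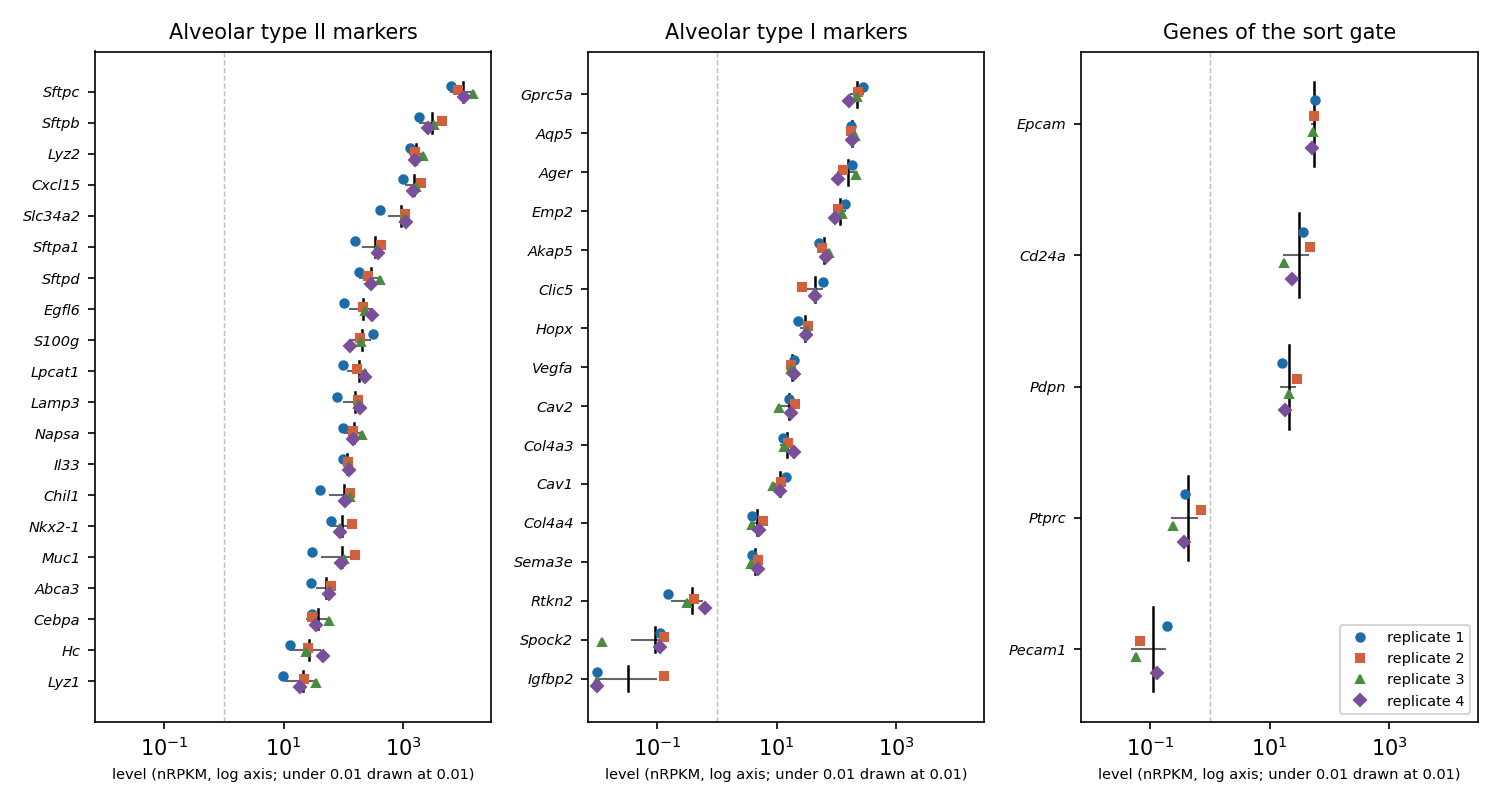
Levels (nRPKM, log axis, values under 0.01 drawn at 0.01) of the 20 type II markers, 16 type I markers and 5 genes of the sort gate in the 4 libraries, with symbols for replicates, a tick for the mean, a line for the mean ± SD (ended at 0.01) and a dashed line at 1. Type II markers run from 21.3 (Lyz1) to 10006 (Sftpc), and 3 type I markers lie below 1.

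Markers of the transitional epithelial state between type II and type I cells were all present, with 16 of 16 at a mean level of at least 1 and a list median of 41.2 ± 16.9 nRPKM. The secreted chaperone gene Clu had 378 ± 81.9 nRPKM and the keratin genes Krt19 and Krt18 had 240 ± 75.1 and 196 ± 71.7. All 23 cell cycle genes had at least 1, led by Mki67 (47.0 ± 21.0), Top2a (36.7 ± 15.8) and Ccna2 (27.2 ± 6.18). Of 15 genes that respond to ERK signalling, 14 had at least 1, led by Phlda1 (190 ± 86.9), the cyclin gene Ccnd1 (138 ± 34.5) and Spred1 (46.6 ± 15.04). Fatty acid synthesis was represented by 12 of 12 genes, with the desaturase genes Scd1 (1395 ± 436) and Scd2 (149 ± 45.5) and the elongase gene Elovl1 (413 ± 123) highest. Cholesterol synthesis had 11 of 12 measured genes at 1 or more, with Sqle (30.1 ± 3.80) and Cyp51 (22.6 ± 3.28) among the highest. The p53 target list had 12 of 15, led by the cell cycle inhibitor gene Cdkn1a (160 ± 42.0), Ccng1 (141 ± 18.0) and Mdm2 (49.1 ± 9.19). All 7 MHC class II genes were present, led by the invariant chain gene Cd74 (529 ± 186), H2-Ab1 (88.6 ± 34.5) and H2-Aa (79.0 ± 35.5; SD, n = 4 throughout).

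Stress and metabolic lists were also expressed. The chaperone gene Hspa5 (330 ± 88.0 nRPKM), Atf4 (54.5 ± 12.1) and Xbp1 (39.1 ± 8.68) led the ER and amino acid stress list. Ldha (203 ± 45.5), Aldoa (87.1 ± 27.8) and Slc2a1 (19.7 ± 5.18) led glycolysis and hypoxia, and Zfp36 (21.3 ± 5.05), Dusp1 (17.0 ± 9.24) and Egr1 (13.0 ± 3.67) led the immediate early genes. Ccn1 (50.6 ± 7.90), Ajuba (7.06 ± 1.49) and Ccn2 (6.50 ± 2.41) led the YAP targets. Of the housekeeping genes, Actb had 687 ± 99.0, B2m 307 ± 171 and Hprt 32.4 ± 5.20, while Gapdh and Ppia had 1.48 ± 0.516 and 1.30 ± 0.576 (SD, n = 4 throughout). Gapdh shares 82.5% and Ppia 38.8% of their 50-base words with other genes. In all, 15 of 31 lists had a median above 95% of random lists: the other ETS, gate, type II, type I, transitional, ERK, cell cycle, MHC class II, fatty acid, cholesterol, p53, immediate early, glycolysis, ER stress and housekeeping lists. With random lists drawn only from expressed genes, 11 lists did so.

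Lists of other cell types were mostly low. Endothelial genes were below 1 for 11 of 13, with Esam (15.4 ± 3.01 nRPKM) and Egfl7 (2.05 ± 0.431) as exceptions and Calcrl next at 0.398 ± 0.396. Ciliated cell genes were below 1 for 8 of 11 (highest Sec14l3 at 26.4 ± 10.3, Dynlrb2 at 1.86 ± 0.805 and Ccdc39 at 1.18 ± 0.280). Neuroendocrine genes were below 1 for 5 of 6 (Uchl1 at 1.18 ± 1.32, Calca at 0.251 ± 0.389, Syp at 0.181 ± 0.111). Erythroid genes were below 1 for 5 of 6 (Alas2 at 1.06 ± 0.426, Hba-a1 and Hba-a2 below 0.1), and mesothelial genes for 4 of 6 (Upk1b at 11.3 ± 7.35, Msln at 10.9 ± 5.34, Gpm6a at 0.119 ± 0.0828). Mesenchymal genes were below 1 for 8 of 14, with Sparc at 471 ± 55.6, Dcn at 5.52 ± 5.92 and Col1a1 at 4.59 ± 2.19. The list medians exceeded 27.3% (endothelium), 39.6% (ciliated), 22.0% (neuroendocrine), 0% (erythroid), 29.8% (mesothelium) and 55.8% (mesenchyme) of random lists.

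Airway and leukocyte genes were also present. The club cell secretory gene Scgb1a1 was abundant and uneven at 350 ± 358 nRPKM, and next in its list were Bpifa1 at 62.2 ± 30.2 and Cyp2f2 at 32.4 ± 15.7. The basal cell keratin genes Krt5, Krt6a and Krt14 had 34.0 ± 27.3, 23.9 ± 16.1 and 19.3 ± 13.1. Of the 8 basal genes, 6 had a mean level of at least 1, and Trp63 and Ngfr lay below 1. The leukocyte list was led by Cd68 (21.7 ± 10.98), Cd14 (15.2 ± 2.81) and Fcer1g (8.64 ± 5.94; SD, n = 4 throughout). Their medians, and that of the YAP targets, lay above 93.4% (club), 90.5% (basal), 93.8% (leukocytes) and 94.5% (YAP) of random lists. Among the remaining lists, the interferon response (69.9%) was led by Bst2 (12.9 ± 3.04), Ddx58 (7.15 ± 0.799) and Ifih1 (5.98 ± 1.52), the lung progenitor list (75.8%) by Id2 (55.1 ± 14.3), the EMT list (53.1%) by Fn1 (30.2 ± 14.7) and Vim (11.01 ± 6.42), and the gastric and gut list (41.1%) by Gkn2 (36.6 ± 7.67) and Ctse (18.4 ± 3.96). The sex gene list had a median above 78.3% of random lists.

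Between libraries, 2 of 13156 tested genes varied more than the trend: Xist, the RNA that coats the inactive X chromosome (adjusted p = 0.000494, edgeR quasi-likelihood dispersion), and Tsix, transcribed antisense to it (adjusted p = 0.00145, same edgeR test). Xist had 0.293, 0.255, 66.3 and 0.784 nRPKM in libraries 1 to 4 and Tsix had 0.376, 0.301, 20.1 and 0.969. Strand use is not stated, so reads of this pair cannot be separated. The filter asked for enough reads in every library, so a gene near 0 in a single library could not be called: 657 genes that passed its cutoff in only 3 libraries were not tested. Among them were the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which were near 0 in library 3 only: Eif2s3y had 15.6, 14.6, 0.243 and 23.2 nRPKM. High Xist with near-absent Y-linked genes argues against library 3 sharing its mouse with libraries 1, 2 and 4. It does not tell whether those libraries came from separate mice. The labels give no sex of the mice. Without the filter, 227 genes were called, among them these 4 (adjusted p of at most 1.8e-14, same edgeR test), and 183 of the 227 were genes that the filter had kept. DESeq2 gave 62 dispersion outliers. Leaving out a library gave from 0 calls (without library 3, with 654 genes at an unadjusted p under 0.05 and 20 DESeq2 outliers) to 6 (without library 1), so the count of 2 depends on the settings. With all 4 libraries, 726 of the 13156 genes had an unadjusted p under 0.05 in the edgeR test. This lies near 1 in 20, and so do the 654 of 13360 genes without library 3. The trended prior was fitted to these same genes, so such a share does not tell chance from real spread between libraries. The common biological coefficient of variation was 24.9%.

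Among gene lists, 13 of 24 spread more between libraries than random lists matched on level. Library 1 had the least of the type II and cell cycle programmes. Its type II markers lay 0.67 log2 units below the mean of the 4 libraries (deviation -0.67), and 18 of 20 were lowest there (Slc34a2 413 against 1028 to 1116 nRPKM). Its cell cycle genes deviated by -0.58, with 22 of 23 lowest there (Mki67 21.3 against 40.6 to 70.4). Transitional markers were highest in library 1 (deviation 0.60, 12 of 16 genes; Lgals3 264 against 59.4 to 122, Nupr1 86.8 against 21.4 to 29.1). The mean of the type I markers ranged over only 0.06 log2 units (adjusted p = 0.980, permutation of lists), with members that went different ways: 4 of 13 were highest in library 1, among them Clic5 (59.4 against 26.7 to 44.2 nRPKM), and Hopx was lowest there (23.0 against 31.1 to 33.2). Adjusted p was 0.000343 for the type II, cell cycle and transitional lists in this permutation test, and these calls rested on library 1: without it the adjusted permutation p was 0.807, 0.565 and 0.267, and the SD of the list mean fell from 0.455 to 0.094, from 0.392 to 0.075 and from 0.416 to 0.141 log2 units. Adjusted over the list alone, 6 transitional genes and no type II or cell cycle gene varied, and none did over all genes.

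Airway, leukocyte and mesenchymal lists followed other orders of the libraries. Club cell genes were highest in library 2 and lowest in library 3, with a 4.39-fold range and 4 of 5 members at each end (Scgb1a1 880 and 93.0 nRPKM, Scgb3a2 20.3 and 0.851). Basal cell genes were highest in library 1 and lowest in library 3, with a 4.26-fold range, 4 of 6 members highest and 6 of 6 lowest there (Krt5 70.6 and 8.22, Krt14 35.1 and 6.10). Leukocyte genes were highest in library 1 and lowest in library 4, with 5 of 10 members highest and 9 of 10 lowest there (Tyrobp 10.95 and 1.94). Laptm5 was as high in library 2 (7.89) as in library 1 (7.81), against 0.947 in library 4. The 10 members are those of 16 listed leukocyte genes that passed the level filter. Ptprc, which did not pass, was highest in library 2 (0.696) and lowest in library 3 (0.245). Mesenchymal genes were highest in library 1 and lowest in library 3, with 3 of 6 members highest and 4 of 6 lowest there (Dcn 14.2 and 0.962). Adjusted p was 0.000343 for club, basal and leukocyte lists and 0.00187 for mesenchyme (permutation of lists), and 5 of 5, 6 of 6, 7 of 10 and 4 of 6 members varied adjusted over the list alone, against none over all genes. The mesenchyme call was lost without library 3 (adjusted permutation p = 0.0887; SD of the list mean 0.243 from 0.432).

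The mean of the MHC class II genes was lowest in library 1 and highest in library 3, with a 2.26-fold range and 5 of 7 members at each end (H2-Ab1 47.4 and 129 nRPKM, H2-Aa 43.9 and 122; adjusted permutation p = 0.000900). Of the others, Cd74 was highest in library 2 (690 against 664 in library 3) and H2-DMa lowest in library 4 (8.09 against 8.54 in library 1). Library 1 also had the lowest cholesterol genes (8 of 11 members; Insig1 9.65 against 16.7 to 29.96; adjusted permutation p = 0.0172) and the highest p53 targets (8 of 12; Gdf15 16.7 against 3.85 to 10.5; 0.00912), immediate early genes (4 of 9; Dusp1 30.8 against 11.4 to 12.9; 0.0118) and YAP targets (5 of 6; Axl 5.28 against 1.01 to 2.63; 0.0330). Each of these 4 calls was lost without library 1, with an adjusted permutation p of 0.858 for cholesterol and YAP, 0.140 for p53 and 0.0778 for immediate early genes. The SD of the list mean then fell to 26.2% of its value for cholesterol and 24.2% for YAP, but kept 65.1% for p53 and 80.0% for immediate early genes. Adjusted over the list alone, 4 of 7 MHC class II genes, 2 immediate early genes and 1 YAP target varied, against none over all genes. The immediate early call was lost without library 4 too (adjusted permutation p = 0.138, with 60.8% of the SD kept). The sex list varied as well (adjusted permutation p = 0.000343), but not without library 3 (0.198; SD 0.224 from 1.345). For the other 11 lists, among them ETS, ERK, fatty acid and interferon genes, the adjusted permutation p ran from 0.0525 to 0.980.

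**Figure D3:**
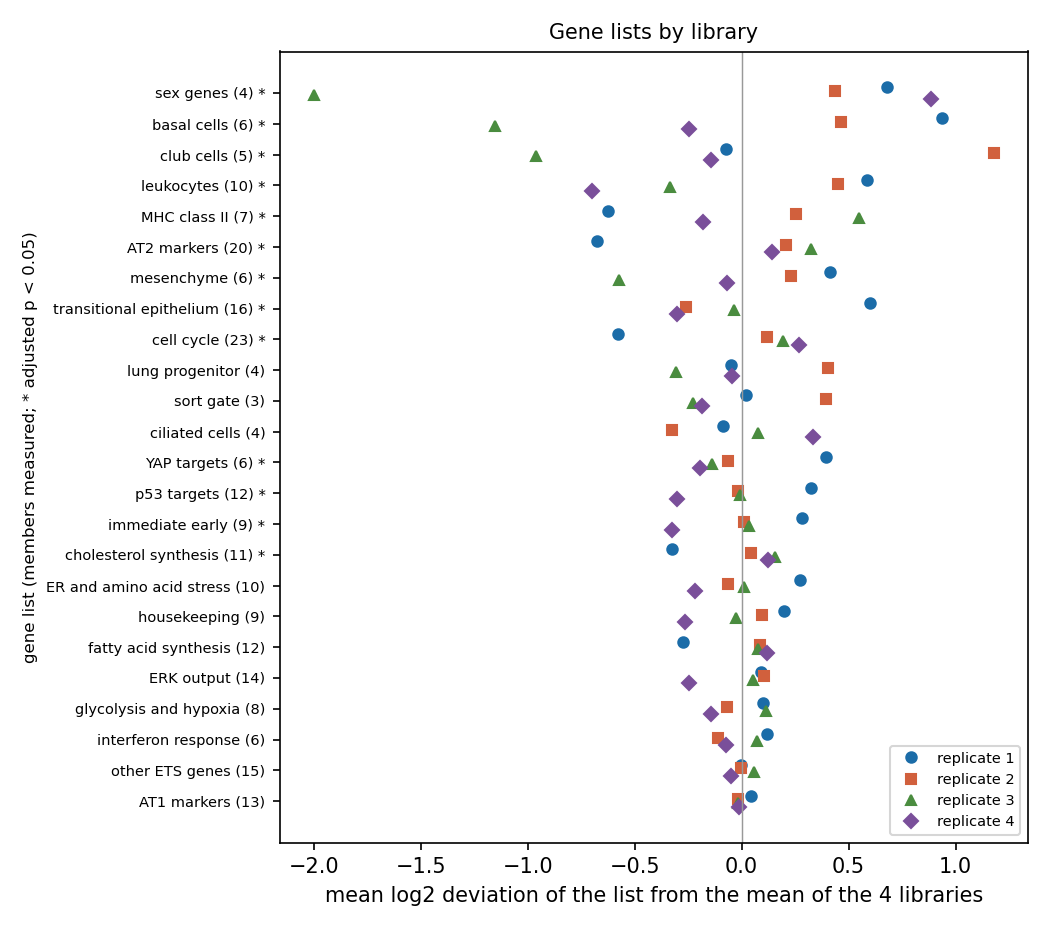
Mean log2 deviation of each of 24 gene lists from its mean over the 4 libraries (horizontal axis, log2 units), with a symbol per replicate and an asterisk at lists with an adjusted permutation p under 0.05. Library 1 has the lowest type II (-0.67) and cell cycle (-0.58) lists, and the type I list spans 0.06.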

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

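The tests below, on library size and on shares of cell types, were chosen after the results were seen. A single library stood far from the other 3 in 16 of 199 results. For independent results not chosen for their spread, 1 in 20 would be about 9.95. These results include lists with their own members and genes named for their spread, so that number is no measure of chance here. Each of the 16 is given with its gap to the nearest library as a share of the whole range.

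Library 3 stood apart in the sex genes. It had the highest Xist (gap share 0.912) and Tsix (0.851), and the lowest Uty (0.952), Eif2s3y (0.853), median level of the sex genes (0.929) and mean deviation of that list (0.845). Library 1 had the lowest Lamp3 (0.918), Slc34a2 (0.917), Abca3 (0.899), Sftpa1 (0.853) and Chil1 (0.835), the lowest fatty acid synthesis list (0.894), the highest Dusp1 (0.874) and the highest type I list (0.944, within a total range of 0.06 log2 units). Library 4 had the lowest ERK output list (0.847), and library 2 the lowest Hspa5 (0.833).

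Type II markers were lower in library 1, with a median log2 difference of -0.96 to the mean of the others and 19 of 20 markers below it. S100g was the exception at 0.87. The other 19 ran from -1.88 to -0.31. The SD of this difference over markers was 0.58, against at most 0.41 with another library taken as the single one. That SD includes S100g and was not computed without it, so it does not show that the markers as a set shifted less alike in library 1. The highest total was 1.12 times that of library 1, but levels are already scaled for library size, so this ratio could not decide on library size as the source. Outside mitochondrial genes, library 1 had 9204693 counts, more than libraries 2 (8189772) and 4 (8119746) and fewer than library 3 (10308763). A lower share of type II cells remains open: it would raise all other cell types alike. The type I list was not among the 5 lists compared, and in library 1 it lay only 0.04 log2 units above the mean of the 4 libraries. Between the lists compared, the gap in library 1 that was largest for its error was of basal (1.25) against club genes (-0.10). It was 2.03 times that error (from the spread over genes and over the other libraries), too little to decide. This test replaced an earlier one that had argued against a lower share from S100g alone (2.52 SD above the other libraries), since a single marker was judged too little. A change of state within the type II cells also stays open and was not tested, and the design, with a single group, gives no biological explanation to test.

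Basal, club and leukocyte genes differed between libraries in different orders. A single lower share of type II cells as the only source would shift these lists alike. Among these lists over the 6 library pairs, the gap largest for its error was from library 4 to library 3. Basal genes differed there by -0.91 and leukocyte genes by 0.37, which is 6.53 standard errors apart. This error covers the spread over genes only, without the spread between libraries used for library 1 above. The gap was also picked as the largest among lists called for their spread. It therefore argues against a single share by gene error alone and does not decide. Different shares of basal-like cells stay open for the basal part. The 8 basal genes with enough reads had a median Spearman rho of 1.00 with their list mean over the libraries. However, 6 of them were the members on which the list was called for its spread. Members of such a list tend to follow its mean, so this test decides nothing. Library 1 had 70.6 nRPKM of Krt5, 35.1 of Krt14 and 36.7 of Krt6a, which was higher in library 2 (38.1). Of the 8 genes, 6 had a mean level of at least 1 nRPKM, and Trp63 and Ngfr lay below it. None of the 8 genes is in another list, and the sort removed cells with podoplanin or CD24 on their surface, which bears on any such cells. A basal programme within cultured type II cells stays open too and was not tested.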

How the results depend on the processing

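The settings added after the data were seen were the variable genes without mitochondrial ribosomal RNA, TMM scaling for list variation and median-ratio scaling for named genes. The differences of Etv5 and Etv4, of Epcam and the 4 excluded gate genes and of type II and type I markers kept their direction in all libraries under every alternative, but with 3 libraries the smallest exact permutation p is 0.25, so these tests say nothing about stability. The number of variable genes was 2, and it was 227 without a filter on low counts and 62 as DESeq2 dispersion outliers; both sets held Xist and Tsix, and the cause was not tested. Leaving out a library gave 0 (without library 3) to 6 (without library 1, adding Scgb3a2, Chil3, Scgb1a1 and an unnamed gene). Against 13 varying lists, leaving out a library gave 6 (without library 1) to 16 (without library 2), and no filter on low counts gave 17; the club, basal, leukocyte and MHC class II lists were called under all 9 alternatives, and 4 of the 11 lists without a call were called under none. Of the values of single lists and genes, 1325 stayed on their side and within their spread, 41 moved (list levels, 28 without length correction and 13 with a pseudocount of 0.1), 12 gained and 10 lost a call. Genes detected fell to 5501 at a level of 5, by construction, and the median Pearson r was 0.957 among expressed genes. No result reversed. TMM and median-ratio scaling moved the median gene by at most 0.016 and 0.004 (log2). No paired analysis was possible because only 1 group was analysed. Depth limits genes under 3 counts, and the simulations show that 4-fold changes in a single library were mostly missed.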

Other observations

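The genes and tests in this part were chosen after the data were seen, except the tests of shared sequence and of general detection and the housekeeping list. Growth factor pathway genes outside the fixed lists were expressed: Nras had 39.8 ± 4.50 nRPKM and Hras 8.88 ± 1.68 (SD, n = 4). Of receptor genes, Fgfr2 had 55.5 ± 22.6 and Met 17.9 ± 2.26, against 5.68 ± 0.768 for Erbb2, 4.80 ± 0.708 for Erbb3 and 1.34 ± 0.521 for Egfr. Fgfr2 was lowest in library 1, at 24.2 against 55.1 to 76.2. The ligand gene Ereg had 24.1 ± 4.00. Of other abundant genes outside the lists, the protease gene Ctsh (885 ± 86.1) and the junction gene Cldn18 (420 ± 40.3) were even and not lowest in library 1, whereas Wfdc2 (437 ± 187) had 627, 392, 531 and 197 in libraries 1 to 4. The 4 surfactant protein genes took 2.04%, 3.63%, 3.98% and 2.98% of the counts outside mitochondrial genes in libraries 1 to 4. The transcription factor genes Klf5 (38.3 ± 11.5), Gata6 (12.4 ± 1.59) and Foxa2 (10.1 ± 2.30) were also present.

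Library 1 had more of the heat shock genes Hspa1a (16.4 against 1.38 to 2.52 nRPKM) and Hspa1b (10.8 against 1.31 to 1.92), of the protease inhibitor gene Timp1 (29.2 against 4.13 to 8.48), of the protease genes Mmp13 (14.6 against 2.25 to 4.70), Mmp3 (6.65 against 0.636 to 2.25) and Mmp10 (8.13 against 1.42 to 2.04), and of the antimicrobial gene Reg3g (13.4 against 1.05 to 2.62). Of other heat shock genes, Hsph1 was also highest there (40.7 against 21.4 to 32.4), but Dnajb1 (21.0 against 17.8 to 23.5) and Hspa8 (20.3 against 15.7 to 20.5) were not. None of these genes passed the adjusted edgeR test of variation. B2m had 562 nRPKM in library 3 and 199 to 241 in the others.

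Ubiquitous genes had implausibly low levels: Gapdh had 1.48 nRPKM and Ppia 1.30, and 79 cytosolic ribosomal protein genes had a median of 4.16. The lowest of the 79 were Rps3a2 (0.0168, 90.2% shared) and Rps3a3 (0.114, 65.1% shared). Whether these are ubiquitous genes was not examined, and the correlation below was not computed without them. Unique alignment to a genome with many processed pseudogenes is a candidate explanation. Across these 79 genes, the share of 50-base words found in another gene and the level had a Spearman rho of -0.56 (Pearson -0.59, permutation p = 1e-05, the smallest that 100000 permutations can give; genes are not independent replicates), and the median level was 17.5 in the 39 genes with the least shared sequence and 2.88 in the other 40. A general failure to detect abundant transcripts is argued against by B2m and Hprt, which share no such sequence and had a median of 170 nRPKM. The mitochondrial COX2, COX3, ATP6, ATP8, ND4L and ND3 genes had likewise low levels of 0.334, 0.145, 0.226, 0.485, 0.176 and 2.06 nRPKM. The other mitochondrial mRNAs ran from 419 (ND2) to 1757 (CYTB), with 1227 for COX1. Shared sequence of the mitochondrial genes was not examined.

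Some identifiers had nearly equal counts. Among 2009 identifiers with at least 4000 counts, 10 pairs had counts within 2% of each other in all 4 libraries, and 7 of these paired a named with an unnamed identifier. How many pairs chance gives was not computed. Tmsb4x had 122926 counts and its unnamed partner 122905.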
